A study of Homo sapiens with 2 samples.

How the data were processed

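RNA-seq was used to compare MDA-MB-231 cells, an established human breast cancer cell line, after exposure to HPTB, an inhibitor of the arginine methyltransferase PRMT5, or to the solvent DMSO, for 4 h at 37 °C. The labels give 5 µM for both treatments. There was 1 library per treatment, so 2 libraries in all. Per the labels' protocols, total RNA was column-purified and DNase-treated, ribosomal RNA was depleted, and libraries were made with a strand-marking total RNA kit.

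The authors deposited 1 table of log2 values with 27710 rows, each a RefSeq transcript, and a column for each library. Per the submitters' processing notes, BWA and hg19 were used, with no version or role stated. The counting program, the annotation release, the use of strand in counting, the filter on low transcripts and the normalization method are not given in the sources used here. The form of the values was settled from the table itself. Raised as powers of 2, every value in both columns was a whole multiple of 1 step per library, within 0.01 read, the step being 1.32 for DMSO and 1.11 for HPTB. The deposited log2 values were therefore logs of whole reads times 1 factor per library, not divided by transcript length. The linear value is called normalized reads here. Dividing by the step returned the reads, which summed over all transcripts to 94981544 for DMSO and 112846226 for HPTB. Reads over exons shared by isoforms are counted for more than 1 transcript in these sums, and the number of sequenced reads was not used here. Kept to 1 transcript per gene, they were 50487830 and 60148699, with a median of 1042 and 1266 reads per gene. No transcript was listed at 0, the smallest count in the better covered library of any transcript was 12 reads, and no transcript lay on the mitochondrial chromosome. Transcripts absent from the table were not analysed here.

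The transcript with the highest mean stood for each of the 14425 gene symbols. Some symbols stood in date form, such as 1-Mar, and such a symbol can stand for more than 1 gene. Values were compared as the authors scaled them. The log2 ratio was the log2 of HPTB over DMSO normalized reads after adding 5 to each, which understates the difference of genes with few reads. Genes needed 20 normalized reads in at least 1 library, which 14421 reached. Fold values are plain ratios of normalized reads, with exact (Clopper-Pearson) 95% intervals made from the recovered reads of the 2 libraries. These intervals cover counting error only. PCR reads without molecular identifiers are not independent molecules, and 1 library per treatment gives no estimate of the spread between cultures. No p-value was therefore computed, nor any SD or standard error between libraries, and no gene was called changed.

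The thresholds, 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took PRMT5 and WDR77, the 10 highest and 10 lowest log2 ratios among protein-coding genes with at least 100 normalized reads in 1 library, and the 2 highest and 2 lowest members of each list. Coding status came from the RefSeq prefix. The plan held 1 setting for counts scaled by size factors and another for log values. The values were both, so they were returned to the linear scale and the first setting was used. The second, a plain difference of logs for genes above the median of all values (10.45 on the log2 scale), was run as an alternative. Lists with at least 5 measured members were described by their median log2 ratio and its percentile among 10000 random lists of equal size drawn from 20 bins of mean expression. This describes the 2 libraries and is no p-value. The spread of a list median is its SD over 1000 resamplings of the list's members, which says nothing of the spread between cultures.

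GC content came from GENCODE release 29 transcripts, matched by RefSeq identifier or by the Ensembl identifier in the table, and covered 98.0% of genes. The trend of the log2 ratio on GC content and log2 transcript length was fitted over genes with at least 100 normalized reads. Coordinates are those of the deposited table on hg19, with the start moved to 1-based numbering. The stored start was 0-based, since end minus start equalled the length in 420 single-exon transcripts and the 1-based form matched in 0.

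The alternatives set out in advance were a pseudocount of 0.5 or 25, rescaling by the median or by a mean trimmed of 30% at each end, no filter or a limit of 100, sums over the transcripts of a gene, thresholds of 1.5-fold and 3-fold, and list means in place of medians. Added after the data were seen were the difference of logs, a correction for GC content and length, random lists also matched on both (in 4 classes of each, or drawn from the 100 genes nearest to each member), and lists without the ATF4 members. The steps were tested on simulated data for the comparison of HPTB with DMSO, with Poisson counts drawn for all 14425 genes from the real means and library sizes. All 50 genes simulated in each direction at 2.5-fold, and all 50 at 3-fold, were found at the 2-fold threshold. Of 14225 genes simulated without a difference, 0 reached 2-fold and 22 reached 1.5-fold from counting error. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.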

Results

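MDA-MB-231 breast cancer cells were profiled by ribosomal RNA-depleted RNA-seq after 4 h with HPTB or DMSO. The design asked which transcripts differ when PRMT5, which methylates arginines of histones and splicing proteins together with its partner WDR77, is inhibited. Each treatment had 1 library, with 50487830 reads over 14425 genes for DMSO and 60148699 for HPTB. With no replicates, the differences below describe these 2 libraries and have no replicate check, and intervals are 95% counting intervals only.

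A small group of stress genes was higher with HPTB. CHAC1, a glutathione-degrading enzyme, was 4.65-fold higher (3.73 to 5.84), and DDIT4, an inhibitor of mTOR signalling, was 3.60-fold higher (3.51 to 3.70). The transcription factor DDIT3, the pseudokinase TRIB3 and BBC3, a pro-apoptotic BCL2 family member, were 2.74-fold, 2.48-fold and 3.28-fold higher. ASAH1, the lysosomal acid ceramidase, was 2.20-fold lower (2.15 to 2.26), and EPN3, an endocytic adaptor, was 4.57-fold lower (3.92 to 5.36). Most genes were close to equal in the 2 libraries, with 97.4% of the 14421 genes above the limit within 1.5-fold.

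In all, 25 genes were at least 2-fold higher with HPTB and 15 at least 2-fold lower. Each of these 40 genes had a counting interval that excluded 1. The threshold all but ensures this at the present depth, so it adds no support. Even at 1.5-fold, intervals excluded 1 for 241 of 244 higher and 122 of 124 lower genes. After removal of a trend on GC content and length, described below, 17 of the 25 and 11 of the 15 stayed at 2-fold. The ribosomal RNA precursor record RNA45S5 and ZNF488 had no GC value, so neither could be corrected. The log2 ratio had a median of 0.00083 over genes and its central 95% ran from -0.44 to 0.53. Only 8 of the higher and 3 of the lower genes reached 1000 normalized reads in a library. With a plain difference of logs among genes above the median of all values, 8 were higher and 1 was lower. That setting drops the pseudocount and raises the limit on reads together.

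The 10 highest protein-coding genes were, in order of log2 ratio, CHAC1, C4orf48, DDIT4, BBC3, RGS16, DDIT3, ZNF503, HIC1, DBNDD1 and TRIB3. Their GC content ran from 50.6% for DDIT3 to 74.6% for C4orf48, with CHAC1 at 66.9% and DDIT4 at 58.1%, against a median of 48.7% over all genes. The ratios and order given here, and those of the 10 lowest below, are before removal of the trend on GC content and length. CHAC1 (NM_024111, chromosome 15, 41245636 to 41248717, plus strand) went from 125 normalized reads with DMSO to 582 with HPTB. DDIT4 (NM_019058, chromosome 10, 74033677 to 74035797, plus strand) had 9152 and 32990 normalized reads, so its ratio rests on far more reads. C4orf48 had 171 and 714 normalized reads, and its 2 transcripts gave log2 ratios of 1.60 and 2.03. DDIT3 had 1667 and 4561 normalized reads in a locus that overlaps MARS on the opposite strand. RGS16, a regulator of G protein signalling, was 3.46-fold higher from 42.2 to 146 normalized reads, and its interval of 2.34 to 5.27 was wide. ZNF503, HIC1 and DBNDD1 also had under 70 normalized reads with DMSO and were 2.76-fold, 2.65-fold and 2.63-fold higher.

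The 10 lowest were GGTLC1, EPN3, C12orf50, C10orf90, NR4A3, BIN2, ZNF488, DOK6, ASAH1 and IL20RB. GGTLC1, of the gamma-glutamyltransferase family, went from 604 to 116 normalized reads (5.20-fold lower, 4.20 to 6.49), which is uncertain because the family has near-identical copies. EPN3 (NM_017957, chromosome 17, 48610048 to 48621111, plus strand) went from 1038 to 227 and C12orf50 from 789 to 200. NR4A3, an orphan nuclear receptor, was 2.69-fold lower (2.03 to 3.60). ASAH1 (NM_177924, chromosome 8, 17913925 to 17941879, minus strand) was by far the most abundant of the 10, with 22333 and 10138 normalized reads, and its 3 transcripts gave log2 ratios between -1.28 and -1.14. ZNF488 overlaps PTPN20B on the opposite strand. Since the use of strand in counting is not given, reads of such overlapping pairs cannot be assigned with certainty.

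**Figure D1:**
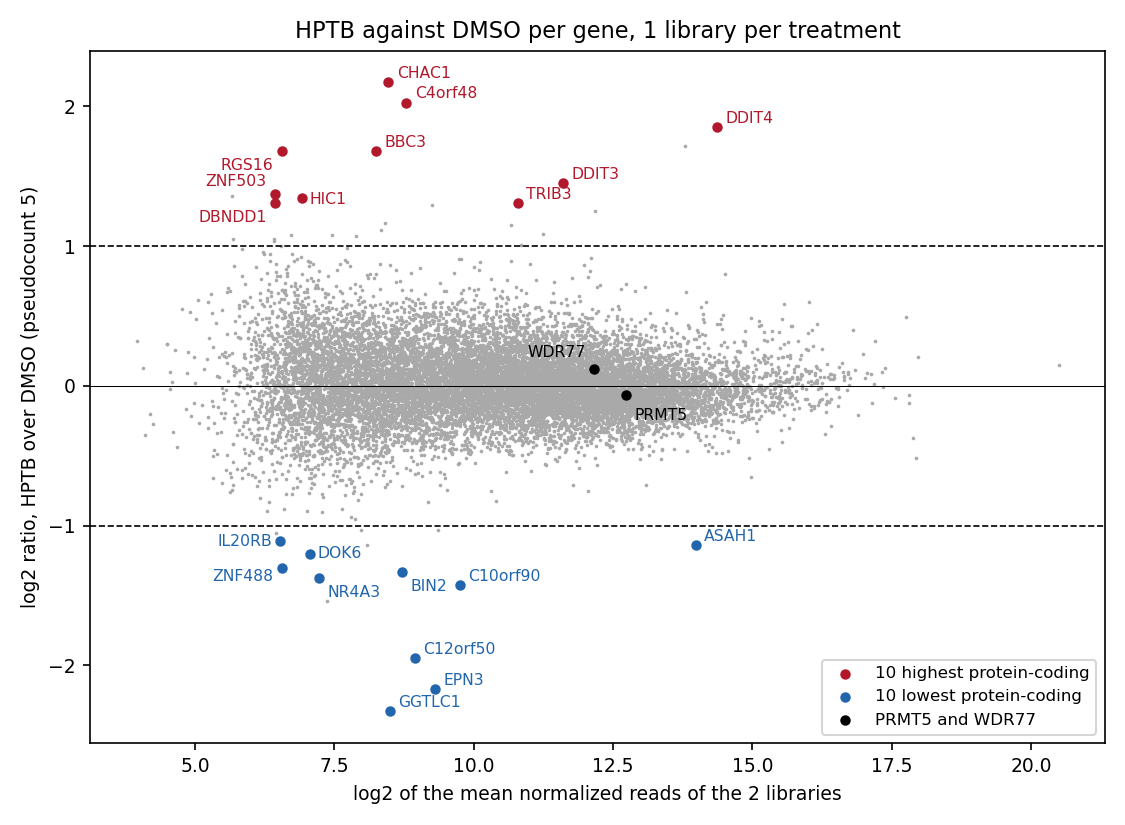
Log2 ratio of HPTB over DMSO (vertical axis, pseudocount 5) against the log2 of the mean normalized reads of both libraries (horizontal axis), with a point per gene and dashed lines at 2-fold. DDIT4 and ASAH1 lie beyond the lines at high read numbers (3.60-fold higher and 2.20-fold lower), while PRMT5 and WDR77 lie near 0 at -0.06 and 0.12.

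The transcripts of PRMT5, the enzyme that HPTB targets, and of its partner were nearly equal in both libraries. PRMT5 (NM_006109, chromosome 14, 23389733 to 23398661, minus strand) had 6961 normalized reads with DMSO and 6664 with HPTB, a ratio of 0.957 (0.922 to 0.994). WDR77 (NM_024102, chromosome 1, 111982512 to 111991830, minus strand), which overlaps ATP5F1 on the opposite strand, had 4394 and 4772, a ratio of 1.09 (1.04 to 1.14). HPTB is an inhibitor of the enzyme, so the PRMT5 transcript checks neither the labels nor whether PRMT5 was inhibited in these cells. The 13 measured genes of PRMT5 partners and other arginine methyltransferases had a median log2 ratio of 0.07, inside the central 95% of random lists. COPRS, a PRMT5-binding adaptor, was the highest of them at 1.40-fold, and PRMT3 the lowest at a ratio of 0.897.

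The genes of the ATF4 and unfolded protein response list were higher as a group. ATF4 is the transcription factor of the integrated stress response. Of 31 measured members, 12 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.36, above all 10000 random lists (percentile 100), and 0.25 after the trend on GC content and length described below was removed. Besides CHAC1, DDIT4, DDIT3 and TRIB3, the 12 were ASNS (asparagine synthetase, 2.38-fold), CEBPB (2.22-fold), SESN2 (2.02-fold), PPP1R15A (1.89-fold), HERPUD1 (1.71-fold), XBP1 (1.63-fold), ATF4 itself (1.60-fold) and SLC3A2 (1.52-fold). The endoplasmic reticulum chaperones of the same list were not among them. HSPA5 had a ratio of 0.900 and HSP90B1 0.915, SEL1L was lowest at 0.894, and CALR and PDIA4 stood at 1.07 and 1.08. This list held 7 of the 25 genes that were at least 2-fold higher. Members beyond the 2 highest and 2 lowest were chosen for naming after their values were seen, as were members of other lists named in that way.

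**Figure D2:**
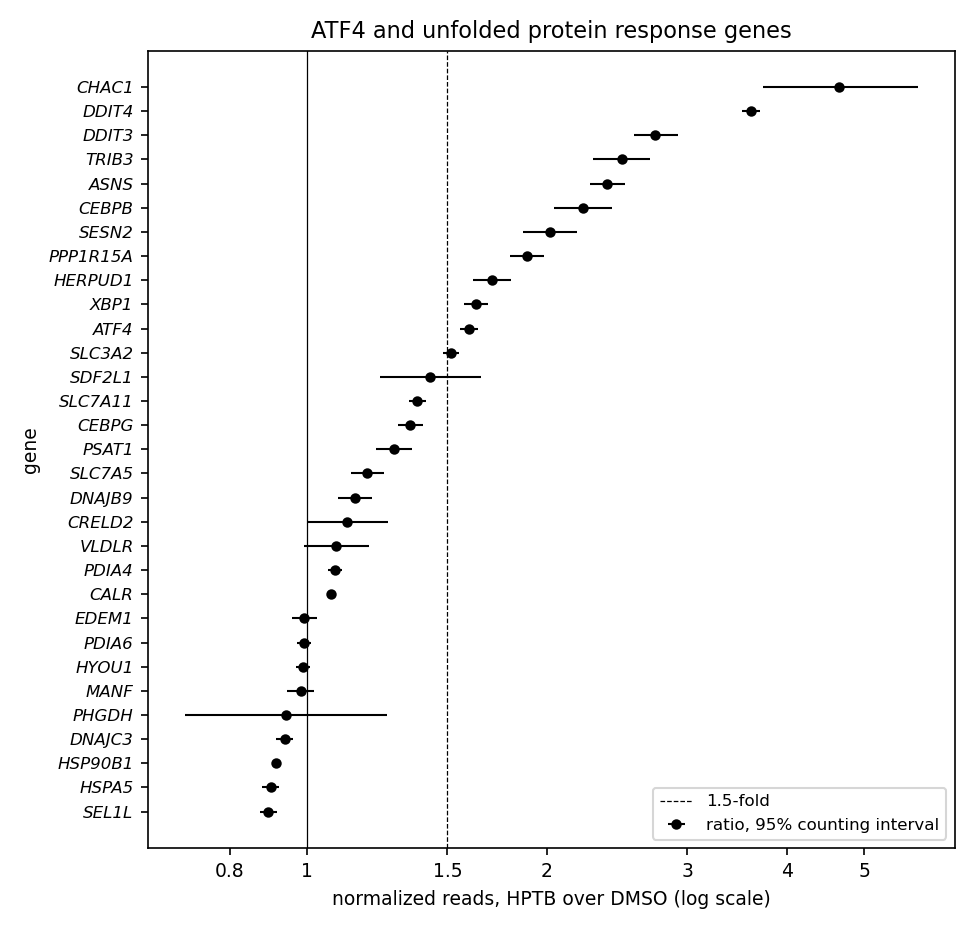
Ratio of normalized reads, HPTB over DMSO, on a log axis for the 31 measured genes of the ATF4 and unfolded protein response list, with 95% counting intervals as bars, a solid line at 1 and a dashed line at 1.5-fold. The 12 genes from SLC3A2 (1.52-fold) to CHAC1 (4.65-fold) lie beyond the dashed line, and HSPA5 and SEL1L lie below 1.

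Across genes, the log2 ratio was related to transcript composition. The 3425 genes with the highest GC content had a median log2 ratio of 0.14, against -0.10 in the 3426 with the lowest. The 3493 genes with the shortest transcripts had a median of 0.09 and the 3492 with the longest -0.08. Pearson's r across genes was 0.38 with GC content (Spearman's rho 0.40, 13703 genes) and -0.27 with log2 length (rho -0.30, 13967 genes), where genes are not independent replicates. A fitted trend on both took up 18.5% of the variance of the log2 ratio. For lists outside the random lists, the median after removal of this trend is given as well.

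Of the 29 lists with enough members, 9 had medians above the central 95% of random lists and 1 below. Lists of independently drawn genes would give about 1.45 outside. Genes of a list are not independent, and some lists share members or differ in GC content and length. The 1.45 is therefore no measure of an excess over chance. Histone genes stood highest, with a median of 0.47 over 10 measured members of 48 listed, among them the linker histones HIST1H1C and HIST1H1E, led by HIST1H2BJ (1.74-fold) and HIST1H2AC (1.51-fold). Their transcripts are short and GC-rich, at a median of 639 nt and 56.1% GC against 3057 nt and 48.7% over all genes, and after the trend was removed the median was 0.24, with 0 members at 1.5-fold. Histone genes have near-identical copies, so single members are uncertain. The list named nuclear long noncoding RNAs had a median of 0.22 over 16 members. Where these RNAs are located in the cell was not tested, so the median does not describe nuclear RNAs as a class. NEAT1, measured on a short record of 3735 nt, was highest at 1.62-fold, followed by SNHG15 at a log2 ratio of 0.59. The lowest members were MALAT1, a nuclear speckle RNA, at a ratio of 0.771 and KCNQ1OT1, which overlaps KCNQ1 on the opposite strand, at 0.746. With the trend removed this list had a median of 0.13.

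Ribosomal protein and oxidative phosphorylation genes had slightly higher medians before that trend was removed. Cytosolic ribosomal protein genes had a median of 0.20 over 39 members, 34 of them above 0 and 0 of them at 1.5-fold, with RPS14 highest at 1.34-fold and RPL11 lowest at 0.890. These transcripts have a median length of 849 nt, and the median was 0.01 after the trend was removed, inside the random lists. Against random lists matched on expression, GC content and length, the list remained above, at 0.20 against an upper bound of 0.13. Ribosomal protein genes share sequence with processed pseudogenes, which leaves single members uncertain. Nuclear-encoded oxidative phosphorylation genes also had a median of 0.20 over 29 members, led by NDUFA1 (1.65-fold, overlapping RNF113A on the opposite strand), with a median length of 1224 nt. Their median was 0.07 without the trend, and 0.20 against an upper bound of 0.12 for the matched random lists. Genes of ribosome biogenesis and other MYC targets had a median of -0.01, with BOP1 at 1.32-fold and CAD at 0.733.

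Mitotic genes were slightly lower as a group. The G2/M list had a median of -0.15 over 30 members (percentile 0.020), 26 of them below 0 and 0 of them at 1.5-fold. CDC25C, a phosphatase that activates CDK1, had a ratio of 0.700, but its 2 transcripts gave log2 ratios of -0.51 and -0.05. The motor protein CENPE had a ratio of 0.724 and MKI67 0.736, while BIRC5 was 1.24-fold higher. These genes have a median GC content of 44.3%, and the median was -0.11 with the trend removed. Genes of G1/S and DNA replication had a median of 0.03, with E2F1 at 1.27-fold. DNA repair genes had a median of -0.09 at percentile 2.89, just inside the central 95%, with XRCC2 at 0.736 and BRCA2 at 0.737.

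Several stress and signalling lists were higher by small amounts. NF-kB targets and cytokines had a median of 0.20 over 26 members, 22 of them above 0, with LIF at 1.38-fold and 0 at 1.5-fold, and 0.13 without the trend. Targets of p53 had a median of 0.15 over 26 members, and the 2 at 1.5-fold or more were BBC3 and SESN2, while MDM2 had a ratio of 0.878. That median became -0.0045 when the GC and length trend was removed, but lay above random lists matched on GC content and length (0.15 against an upper bound of 0.12). Immediate early genes had a median of 0.13 over 27 members, with 6 at least 1.5-fold higher, among them ATF3 (2.27-fold, with log2 ratios of 0.67 to 1.30 over its 6 transcripts) and JUNB (1.77-fold), and with NR4A3 lower. Without the trend their median was 0.06, inside the random lists, and 3 were at least 1.5-fold higher. BCL2 family and apoptosis genes had a median of 0.12 over 28 members, with BBC3 alone at 1.5-fold and BCL2L11, another pro-apoptotic member, at 0.751, and 0.10 without the trend. Some genes stand in several lists, such as BBC3 and SESN2.

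**Figure D3:**
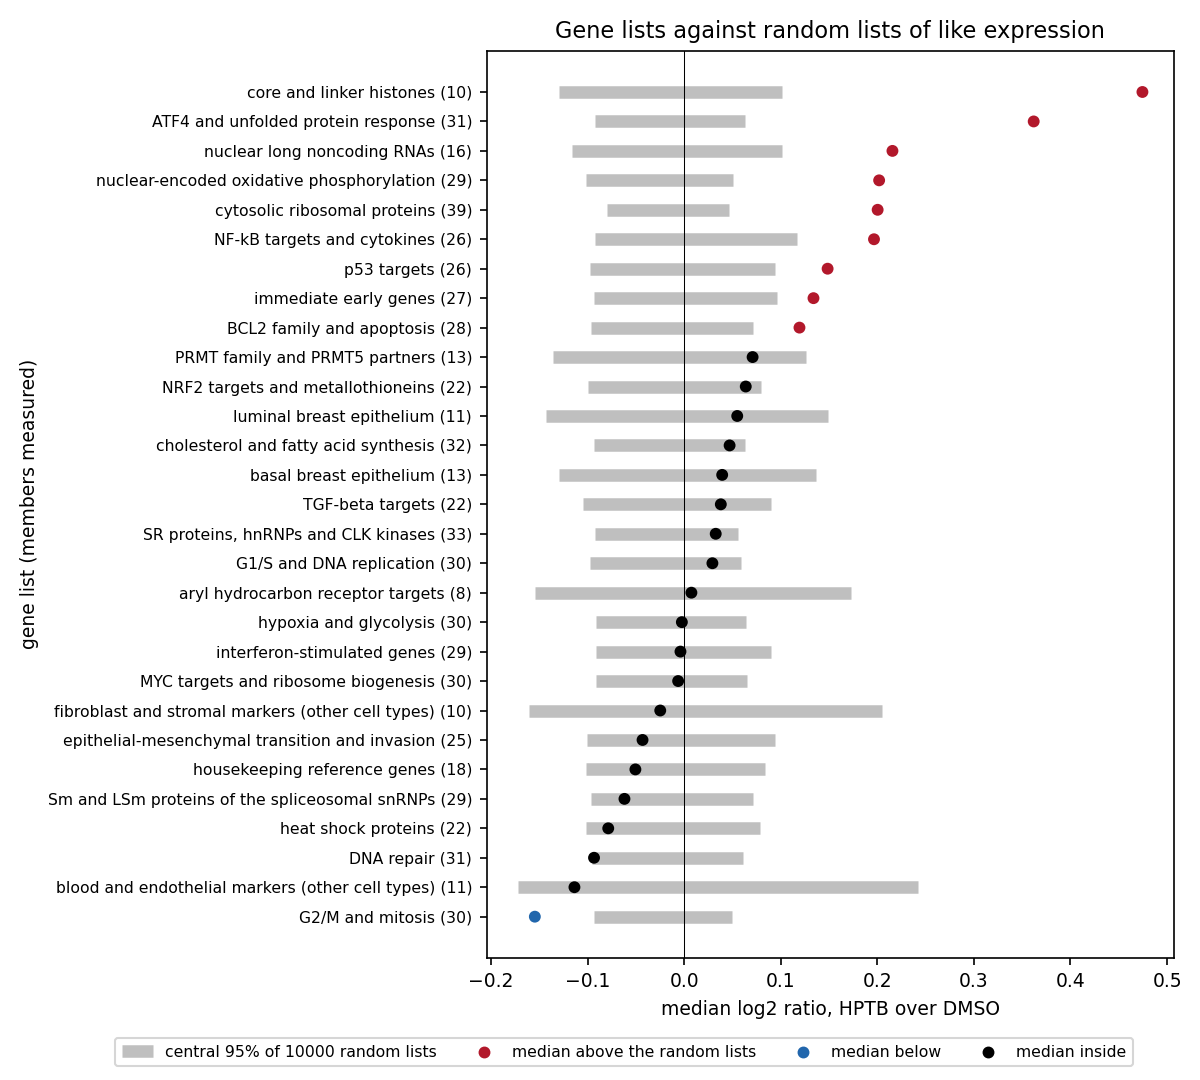
Median log2 ratio of HPTB over DMSO for the 29 gene lists (points) with the central 95% of 10000 random lists of like mean expression (grey bars) and the number of measured members in parentheses. The ATF4 list (0.36) and histones (0.47) lie farthest above their bars, and the G2/M list (-0.15) is the one below.

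The remaining lists had medians inside the central 95% of random lists. Among genes tied to splicing, Sm and LSm protein genes had a median of -0.06 over 29 members, 14 of them above 0, and a mean of 0.02. LSM7 was at 1.42-fold and GEMIN6 at 0.793. SR proteins, hnRNPs and CLK kinases had a median of 0.03 over 33. Heat shock genes had -0.08, with 19 of 22 below 0 and the constitutive chaperone HSPA8 at 0.700. After the GC and length trend was removed, the heat shock median (-0.12), that of Sm and LSm genes (-0.092) and that of epithelial-mesenchymal transition genes (-0.10) lay below the random lists. NRF2 targets had a median of 0.06, interferon-stimulated genes -0.0038, TGF-beta targets 0.04, epithelial-mesenchymal transition genes -0.04, hypoxia and glycolysis genes -0.0023, cholesterol and fatty acid synthesis genes 0.05 and aryl hydrocarbon receptor targets 0.0076. In the TGF-beta list 4 of 22 members were at least 1.5-fold higher, led by ID3 (1.81-fold), an inhibitor of differentiation factors, and 2 were after the trend was removed. IFI44L had a ratio of 0.642 and EGLN3, an oxygen-sensing hydroxylase, 0.609.

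Among markers of cell identity, luminal and basal breast epithelial genes had medians of 0.05 and 0.04, inside the random lists. With the trend removed the luminal median was -0.090, with 8 of 11 members below 0, and the basal median 0.07, both still inside. Single members reached 1.5-fold, with XBP1 of the luminal list 1.63-fold higher, the basal keratin KRT17 at a ratio of 0.638 and the endothelial PECAM1 1.68-fold higher. KRT17 and PECAM1 had under 70 normalized reads in each library. Markers of other cell types, fibroblasts at -0.02 and blood and endothelium at -0.11, lay inside the random lists, as did housekeeping genes at -0.05. Among the latter POLR2A was lowest at a ratio of 0.735 and RPLP0 highest at 1.25-fold. Of the small structural RNAs, SCARNA12 alone was measured (1.61-fold higher), in a locus shared with PHB2, and 0 mitochondrially encoded mRNAs were measured.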

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

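The difference of logs, the GC and length correction, both ways of matching random lists on GC and length, and the lists without ATF4 members were tests chosen after the results were seen. With 1 library per treatment no library could be left out, and no paired analysis was possible because no groups share replicates. Every alternative set out in advance was run. The 2-fold counts of 25 higher and 15 lower ran from 17 to 29 and from 11 to 15 over other pseudocounts, scalings, limits, sums of transcripts and the GC and length correction. They were 244 and 124 at 1.5-fold, 6 and 3 at 3-fold, and 8 and 1 with the difference of logs, which drops the pseudocount and leaves out genes under the median of all values. Both rescalings moved log2 ratios by under 0.01. Of 1139 alternative values of named genes, 1076 stayed within the counting interval, 63 moved out of it and 0 changed sign against an interval that excluded 0. Of 374 alternative list values, 354 kept their place. That count includes settings that could hardly move a list, such as both rescalings and the lack of a filter, which adds 4 genes. With GC and length corrected, p53 targets changed sign to -0.0045, immediate early genes (0.062) and ribosomal proteins (0.012) came inside the random lists, and Sm and LSm proteins (-0.092), heat shock genes (-0.12) and epithelial-mesenchymal transition genes (-0.10) came out below. With random lists matched on both, in classes or by nearest genes, immediate early genes (0.13) came inside, and Sm and LSm proteins (-0.062), heat shock genes (-0.079) and housekeeping genes (-0.049) lay below. Epithelial-mesenchymal transition genes (-0.043) stayed inside these matched lists. With the difference of logs, immediate early genes (0.054) came inside, and heat shock (-0.13) and DNA repair genes (-0.12) lay below. As means, heat shock (-0.12) and DNA repair genes (-0.076) lay below and NRF2 targets (0.11) above. The cause was not tested. Genes under 100 normalized reads have wide counting intervals, which limits their ranks.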

Other observations

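The lists of amino acid (with and without members of other functions), endoplasmic reticulum, lysosomal and glucocorticoid genes, the correction for GC content and length and the matching on both, and the count of intervals above 1 were tests chosen after the results were seen, as was the rule that weighs the correction with the matched lists. The rule that a list median had to pass its bound by more than its spread was also set after values were seen. Other known ATF4 targets, most of them genes of amino acid supply and in none of the fixed lists, had small ratios mostly above 1. Of 31 measured, 26 had log2 ratios above 0 and 2 were at least 1.5-fold higher, and the median was 0.22, against a central 95% of -0.04 to 0.10 for random lists matched on expression, length and GC content. The cysteine-producing enzyme CTH was 1.55-fold higher and the stress protein NUPR1 1.51-fold, but the 2 transcripts of NUPR1 gave log2 ratios of 0.25 and 0.59. The mitochondrial folate enzyme MTHFD2 was 1.43-fold higher, the serine synthesis enzyme PSPH 1.43-fold and the amino acid transporter SLC38A2 1.40-fold. The tRNA synthetases AARS, CARS and YARS were each 1.34-fold higher, while EPRS and WARS had ratios of 0.949 and 0.946. Without NUPR1, STC2, JDP2 and EIF4EBP1, which have other functions, the median was 0.18 over 27 genes. With the GC and length trend removed, the medians were 0.168 for the 31 genes (upper bound 0.066) and 0.129 for the 27 (upper bound 0.069).

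RNA45S5, the record of the ribosomal RNA precursor with the mature sequences in it, was 3.29-fold higher with HPTB, from 6582 to 21654 normalized reads, in libraries depleted of ribosomal RNA, and precursor and leftover mature RNA were not separated. Lysosomal genes had a median log2 ratio of 0.18 over 31 members, with 23 above 0, led by CLN3 (1.40-fold) and GAA (1.34-fold), while CTSK had a ratio of 0.648. Their median was above matched random lists (0.00014 to 0.16) by less than its spread over members (0.05), and 0.09 after removal of the GC and length trend, where the upper bound was 0.07 and the spread 0.03. ASAH1, a lysosomal enzyme outside the list, was 2.20-fold lower. GDF15, a stress-induced cytokine, was 2.47-fold higher, and TSC22D3, a glucocorticoid-induced gene, 2.13-fold higher. Other glucocorticoid targets had a median of 0.06 over 14 members, inside random lists, and 8 of them were above 0, from ERRFI1 at 1.40-fold and KLF9 at 1.38-fold to SGK1 at 0.775 and FKBP5 at 0.778.

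The higher ATF4 list had several explanations to weigh. Counting noise is argued against by 20 of all 31 members having counting intervals above 1 (4 lay below 1). Counting error would give about 0.775. At this depth small ratios also exclude 1, such as P4HB outside the list at 1.08 (1.06 to 1.10). The count therefore bears on counting error only. The GC and length trend as the whole cause is argued against by the list median after its removal. That median was 0.25 (spread over members 0.17), against an upper bound of 0.07 for random lists. A broad increase of endoplasmic reticulum chaperone and degradation genes is argued against by 32 of them outside the list. Their median was -0.053 (spread 0.032), with 11 above 0, up to SSR4 at 1.33-fold. After removal of the GC and length trend it was 0.024 (spread 0.023), inside the random lists (-0.05 to 0.06) as before. HERPUD1 and XBP1 inside the list were 1.71-fold and 1.63-fold higher, so part of that response stays open. An amino acid arm of the ATF4 response stays open too. The 27 amino acid genes, with a median of 0.18 (spread 0.08), lay above the upper bound of 0.10 by just under that spread. After removal of the GC and length trend their median of 0.13 (spread 0.07) was likewise above a bound of 0.07 by less than its spread. All 31 targets, at 0.22 (spread 0.08), lay above theirs by more. A difference between cultures or library batches cannot be told apart from HPTB, nor PRMT5 inhibition from another action of the compound, with 1 library per treatment.

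The lower G2/M list was also set against the GC and length trend. Its median was -0.15 (spread 0.02) before and -0.11 (spread 0.04) after removal of the trend, against a lower bound of -0.05 for random lists, which argues against the trend as the whole cause. A smaller share of mitotic cells in the HPTB culture may account for the rest, which was not tested, and 1 library per treatment leaves culture differences open.

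The higher ribosomal protein and oxidative phosphorylation lists were set against the same trend. The ribosomal protein median was 0.20 (spread 0.05) before and 0.012 (spread 0.032) after removal of the trend, inside the random lists, but 0.20 lay above the upper bounds of random lists matched on expression, GC content and length, 0.13 in classes and 0.15 by nearest genes. These controls disagree, so whether the trend could account for this list stays open, and GC content was not separated from length. The oxidative phosphorylation median was 0.20 (spread 0.06) against matched upper bounds of 0.12 and 0.13, but after removal of the trend 0.069 (spread 0.029) lay too near the bound of 0.064 to decide, so the trend stays open here as well. Culture and library differences stay open for both, and no biological explanation was tested.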
